A study of Homo sapiens with 4 samples.

How the data were processed

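Total RNA of LNCaP cells was profiled on 1-colour Agilent exon microarrays, with 1 array per RNA sample and 4 arrays in all. Per the labels' protocols, stable clones carrying either an empty vector or a short hairpin RNA against CRISP3 were selected on puromycin and taken at different passages. The RNA was copied with a primer for the whole transcript and labelled with Cy3 in the antisense RNA made from it. The empty vector clone was sampled at passages 2 and 15, and the knockdown clone at passages 2 and 13. The labels describe the arrays of a group as a clone at different passages. Single-gene p-values of the knockdown comparison therefore measure the spread between passages and arrays, not the spread between independently derived clones. Those of the passage comparison measure how far the passage change differed between the clones. List p-values from camera and family p-values from Fisher's exact test, both below, set genes against other genes. They do not measure a spread between independently derived clones either.

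Per the file headers, the scanner images were quantified with Agilent Feature Extraction 11.5.1.1 on array design 028679, whose probe positions refer to hg19 (GRCh37). The submitters' processing notes also name Feature Extraction 11.5. Per the file headers, the deposited intensity values used here are the processed Cy3 intensities, which the software had background-subtracted and corrected for trends across the slide. They were not scaled between arrays. The mean spot intensity and the median local background intensity, also deposited, served for 1 alternative. The authors' deposited value table holds log2 values, and its scale was found from the files. Each of its columns has a 75th percentile of 0 within rounding, and between 99.97% and 99.98% of its probes per array lie within 0.01 of the scanner value after the same scaling. Its column medians are -2.04 and -1.98 for the empty vector arrays and -2.02 and -2.00 for the knockdown arrays. It holds no centring across arrays, and its direction is that of the intensity itself. The deposited files hold no test by the authors.

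All 4 arrays lie on 1 slide and were scanned together, so slide and scan could not act as batches. Each array holds 174458 non-control probes, 150 of them spotted 10 times. The number of arrays limits the precision, which no depth of reading can improve. The 75th percentile of intensity was 396 and 485 on the empty vector arrays and 515 and 602 on the knockdown arrays. Between 74.6% and 79.0% of probes were well above background on an array. Between 73 and 141 spots per array carried an outlier flag and were left out, and 0 spots were saturated. No probe value was identical across a pair of arrays over the whole file. Signal rose towards the 3′ end of transcripts by 0.21 to 0.24 log2 units per kb on all arrays, so this slope did not set a group apart.

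Values were computed as log2 of the processed intensity minus the array's 75th percentile over non-control probes. Spots of a probe were averaged. A probe entered when it was well above background on both arrays of at least 1 group, which 133352 probes did. A gene's value was the mean over its entering probes, with a median of 5 probes per gene, grouped by the gene name in the files. This gave 16863 gene units, of which 290 carry only a probe ID or transcript accession. Gene names of the array design are old. Accessions of 16262 units matched a single symbol in a RefSeq table of a later assembly (GRCh38.p14), used for names alone, and 1609 symbols were updated. Near-identical gene copies can share a probe's target. Values of SPACA5 and SPACA5B, XAGE1A and its copies, PTPN20A, the AKR1C and UGT2 genes, the MAGEA genes and the metallothioneins are uncertain in that respect.

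Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on gene-level log2 values), with Benjamini-Hochberg adjustment and a threshold of 0.05. The R package data.table (version 1.17.8) handled the tables, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. All adjusted p-values of single genes are limma's. Knockdown was compared with empty vector on all arrays without a block, which leaves 2 residual degrees of freedom before moderation. Late was compared with early passage in an additive model with the vector group as a term, which leaves 1. The interaction of knockdown and passage leaves none and was not tested. Only a bound exists where a group's probes for a gene were not well above background on either array, or where the group's mean lay below the lowest signal among probes well above background (-5.36 in the vector group and -5.54 in the knockdown group). Folds are then given as "at least", from the bright group's mean against the higher of the dim signal and the lowest signal among probes well above background on each array.

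A total of 29 gene lists, the tests, the naming rule and the alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists, all of which had at least 5 measured members. Camera with an estimated correlation and fry were alternatives. The estimated correlation rests on 2 residual degrees of freedom in the knockdown comparison and on 1 in the passage comparison. It called 0 of 29 lists in either, so a call lost in that setting alone decides little about a list. ANXA1 and KLK3 were known beforehand as genes this study reported on, so the lists holding them are not independent of these samples. Genes were named by rule. CRISP3 came first, then the 12 largest rises and 12 largest falls among genes with a symbol, adjusted p under 0.05, at least 2 probes and the same direction at both passages. Where none passed, the 6 genes each way with the smallest p and the same direction in both clones were taken. From each list came 2 to 4 members with the largest changes past the threshold, or, failing that, up to 3 with the largest changes. KLK3, KLK2, ANXA1 and MSMB were named in any case. A few named genes, 1 of the lists and the results that need them are not reported here.

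The procedure was tested on simulated data for the knockdown comparison, with 16863 genes and 200 changed genes per run. Where each gene kept its spread after limma's moderation, 94% of changes of 1 log2 unit and 100% of changes of 2 log2 units were called. In those runs 11.2% of calls were false, above the 5% aimed for. Where spreads were drawn from the fitted prior, 55.5% of changes of 1 log2 unit were called and 6.68% of calls were false. List calls were counted only in runs of the first kind, where genes kept their moderated spread. Over 4 such runs with no shifted list, 1 list call was false, and a list shifted by 0.7 was called. Errors were drawn independently for each gene, so these runs do not show how often lists with correlated members are called falsely. Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the filter on dim probes, the gene summary, an intensity trend with a robust prior, the authors' value table, a replicate block, an untested 2-fold rule and leaving out each array.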

Results

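The series asked which genes differ when CRISP3 is knocked down in LNCaP, an established, androgen-responsive human prostate cancer cell line. CRISP3 encodes cysteine-rich secretory protein 3, a secreted protein of the prostate and other glands. Total RNA of an empty vector clone and of a clone stably expressing a short hairpin RNA against CRISP3 was hybridised to exon arrays. The 2 empty vector arrays came from passages 2 and 15, and the 2 knockdown arrays from passages 2 and 13. All folds below are ratios of group means over 2 arrays each, and SE is the standard error of the log2 difference. Across genes, arrays of a clone correlated at 0.993 in either group, and arrays of different clones at 0.979 to 0.984.

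CRISP3 itself was lower in the knockdown clone at both passages. It was already dim in the vector clone, where its level ranked at percentile 7.74 among tested gene units. Over its 4 usable probes on chromosome 6 (hg19, 49696178 to 49705097 for all CRISP3 probes) it fell at least 1.76-fold (log2 -1.56, SE 0.22, limma adjusted p = 0.0151). The difference was -1.25 at early and -1.88 at late passage. The 4 usable probes lay lower after scaling, by unequal amounts. The probe at 49703217 to 49703276 had a mean intensity of 16.3 in the vector clone and 2.47 in the knockdown clone, where it was not well above background on either array. The probe nearest the 5′ end, at 49705038 to 49705097, was nearly equal in both groups, at 55.2 against 64.5 before scaling and 1.09-fold lower after it. The call was lost when the gene was summarised by the median of its probes (adjusted p = 0.0676) or by median polish (0.0810), within a range of 0.000756 to 0.0810 over 15 alternatives. With normexp background correction the difference shrank to -0.47, and with probes well above background on all arrays to -0.74, which is below the bound given above in size.

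**Figure D1:**
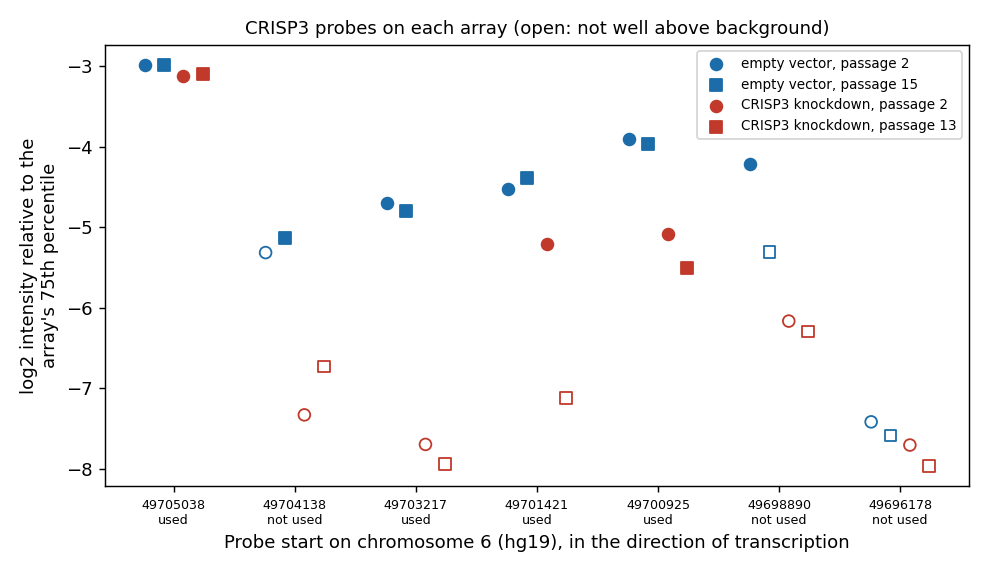
Intensity of each of the 7 CRISP3 probes on each array, as log2 relative to the array's 75th percentile, ordered from the 5′ to the 3′ end of the gene. Colour marks the group, the shape marks the passage, and open symbols mark spots not well above background. The probe at 49705038 was nearly equal in both groups and the probe at 49703217 was well above background on 2 vector arrays and 0 knockdown arrays.

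The largest fitted differences between the clones were in FUCA2, a secreted fucosidase, on chromosome 6 (143816912 to 143832610), which was at least 31.3-fold higher (log2 5.88, SE 0.44, adjusted p = 0.00246), and in KLK3 on chromosome 19 (51358198 to 51364020), which encodes prostate-specific antigen and was 40.0-fold lower (log2 -5.32, SE 0.34, adjusted p = 0.00189). All 7 FUCA2 probes were higher and all 8 KLK3 probes lower. HENMT1, a methyltransferase of small RNAs, rose at least 10.8-fold (log2 4.65, SE 0.54, adjusted p = 0.00818). ANXA1, the phospholipid-binding annexin A1, rose at least 4.94-fold (log2 3.07, SE 0.22, adjusted p = 0.00219), with all 9 probes higher. VIM, the intermediate filament protein vimentin, rose 7.80-fold (log2 2.96, SE 0.20, adjusted p = 0.00201). Among the other leading rises were HTATIP2 (6.53-fold), the phosphoinositide phosphatase family member MTMR8 (6.10-fold), the neurotrophic factor co-receptor GFRA1 (at least 2.79-fold) and the phospholipase PLCB1 (4.44-fold), for which all 30 probes were higher. SYT1, a calcium sensor of vesicle release, rose at least 2.01-fold, since its probes were not well above background in the vector clone. The rest were the acrosome genes SPACA5B (at least 3.33-fold) and SPACA5 (at least 3.09-fold) and the cilia gene CFAP300 (4.07-fold).

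The leading falls beside KLK3 were spread over secreted enzymes, germ cell genes, signalling genes and caspases. DNASE1L3, a secreted nuclease, fell 17.0-fold (log2 -4.09, SE 0.26). The cancer-testis gene XAGE1A fell 13.2-fold, GNAI1, a subunit of inhibitory G proteins, 10.7-fold, and the inflammatory caspases CASP4 and CASP5 fell 9.33-fold and 9.23-fold. EFNA5, an ephrin ligand, fell 9.12-fold and BMPR1B, a receptor for bone morphogenetic proteins, 8.17-fold, with all 10 probes lower. ADAM2 fell at least 4.93-fold, SCRG1 at least 4.97-fold, PTPN20A at least 2.69-fold and TNFSF10, the death ligand TRAIL, at least 2.36-fold, each being not well above background in the knockdown clone. Adjusted p for these 12 falls lay between 0.00168 and 0.00756 in limma. For the 12 rises it lay between 0.00168 and 0.0386. Leaving out the early knockdown array ended the calls of FUCA2, HENMT1, HTATIP2, MTMR8, CFAP300, SPACA5, SPACA5B and GNAI1, with adjusted p up to 0.256. Without the late knockdown array HENMT1, HTATIP2, CFAP300, SPACA5 and SPACA5B lost theirs (adjusted p up to 0.250). Without the early vector array GFRA1 and SPACA5B lost theirs (adjusted p up to 0.546), and without the late vector array all 24 calls held.

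In all, 801 of 16863 gene units passed the threshold, 228 higher and 573 lower in the knockdown clone, and 436 of them differed at least 2-fold. The share of lower genes was 71.5%, and under quantile scaling it was 59.5% (333 higher and 490 lower). It was 49.4% without the early and 54.9% without the late knockdown array, and 88.1% without the early and 63.0% without the late vector array. An unadjusted p under 0.05 was reached by 3694 units. Of the 520 called genes with 3 or more probes, 406 had all probes on 1 side. The count of 801 depended on which array was left out. It fell without either knockdown array and rose without either vector array. Each such fit leaves 1 array in a group and takes its spread from the other group alone. It therefore cannot show what a single array contributed. With 1 clone per group, a difference between the clones and an effect of CRISP3 loss cannot be told apart.

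The difference between the clones recurred across passages. Across genes, the knockdown minus vector difference at early passage correlated at 0.63 with that at late passage, and 64.9% of gene units had the same sign. These differences share no array. Genes are not independent replicates, so no p is given. ANXA1 was higher by 3.17 at early and 2.96 at late passage, and KLK3 lower, at -5.83 and -4.81. Without the filter on dim probes the correlation was 0.48.

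**Figure D2:**
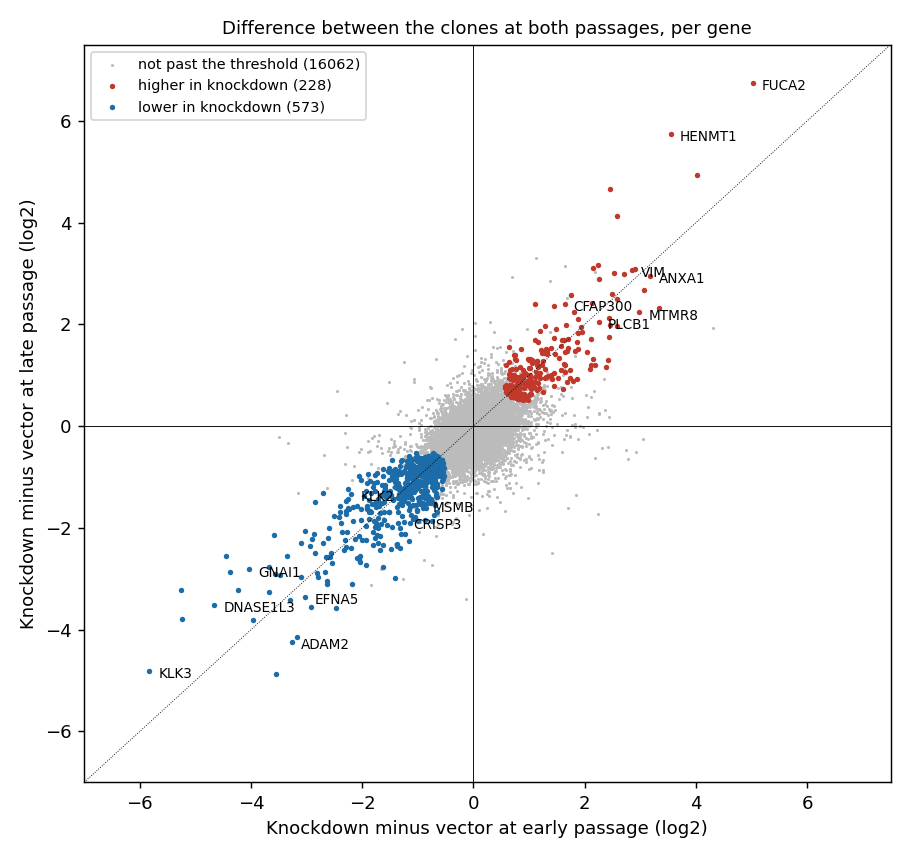
Knockdown minus vector difference of each gene unit at early passage (horizontal axis, log2) against the difference at late passage (vertical axis, log2), with 228 genes higher and 573 lower past the threshold in colour and the rest in grey. The dotted line marks equal differences. FUCA2 and KLK3 lie at opposite ends, and the correlation across genes is 0.63.

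Androgen-regulated genes were lower as a list (camera adjusted p = 1.05e-05). The call was lost with fry (adjusted p = 0.108) and in camera with an estimated correlation (adjusted p = 0.724). The latter was the highest over 17 alternatives, which went down to 7.42e-08. Of 31 measured members, 0 rose, 11 fell and 20 did not pass, and 14 fell when adjusted over the list alone. Beside KLK3, the falls included KLK2 (3.40-fold, log2 -1.77, SE 0.27, adjusted p = 0.0218), which lies beside KLK3 on chromosome 19, MAF (3.54-fold) and STEAP4, a metalloreductase (at least 2.53-fold). TMPRSS2 (-0.57) and KLK4 (-0.01) did not pass. MSMB, which encodes a secreted protein of the prostate, fell 2.33-fold (adjusted p = 0.0268). KLK3 was known from the study, so this list is not independent of these samples. Without the early knockdown array 1 member fell, and without the late one 3.

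Genes of steroid and androgen metabolism were also lower as a list (camera adjusted p = 1.05e-05). The call was lost with fry (adjusted p = 0.108) and in camera with an estimated correlation (adjusted p = 0.724). Of 25 measured members, 0 rose and 11 fell, with 14 falling when adjusted over the list alone. AKR1C1 fell at least 3.92-fold and AKR1C3 6.25-fold, both reductases of steroids. HSD17B2, which oxidises sex steroids, fell at least 3.30-fold, and UGT2B28, which conjugates steroids to glucuronic acid, 4.51-fold. AKR1C genes lie side by side on chromosome 10 and UGT2 genes on chromosome 4, and their probes can read several copies. Falls in this list are therefore not all independent of each other. UGT2B15 (0.14), UGT2B17 (0.25) and SRD5A1 (0.40) did not pass. Without the early knockdown array 5 members fell, and without the late one 6.

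Annexins and S100 proteins, which bind calcium, moved apart. ANXA1 was the only 1 of 18 measured members to rise, and 6 fell, among them ANXA13 (at least 2.27-fold), S100A14 (2.72-fold) and S100A4 (2.42-fold). ANXA13 was at 0.73 without the late knockdown array. The list as a whole was lower (camera adjusted p = 0.00700; fry adjusted p = 0.0119; adjusted p = 0.724 with an estimated correlation). Adjusted over the list alone, 1 rose and 7 fell. ANXA1 was known from the study, so the list is not independent of these samples. The list's call was lost without the early knockdown array (adjusted p = 0.170, 0 members falling) and without the late one (0.124, 1 falling), and in genes with at least 3 probes (0.515), within a range of 0.00271 to 0.724 over 17 alternatives.

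Basal cell markers of the prostate were lower as a list (camera adjusted p = 0.00554). The call was lost with fry (adjusted p = 0.203) and in camera with an estimated correlation (adjusted p = 0.950). Of 16 measured members, 4 fell and 0 rose, and 7 fell when adjusted over the list alone. They were SFN (3.95-fold) and the keratins KRT14 (3.32-fold), KRT15 (2.56-fold) and KRT17 (1.92-fold, with 3 probes higher and 3 lower). KRT5 (-0.24) and TP63 (0.09) did not pass. Without the early knockdown array 1 member fell, and without the late one 3. Cancer-testis genes were lower as a list (camera adjusted p = 0.0344; adjusted p = 0.884 with an estimated correlation), with 4 of 18 members falling and 0 rising. These were XAGE1A, MAGEA8 (at least 4.53-fold), MAGEA4 (3.56-fold) and MAGEA1 (2.70-fold), and adjusting over the list alone gave the same number. The cancer-testis call was lost in 7 of 17 alternatives. Beside the estimated correlation these were quantile scaling (adjusted p = 0.102), no filter on dim probes (0.0851), probes well above background on all arrays (0.111), genes with at least 3 probes (0.434), fry (0.112) and leaving out the early knockdown array (0.0809), within a range of 0.00385 to 0.884 over 17 alternatives. Ribosomal protein genes were higher as a list by a median of 0.17 (camera adjusted p = 1.05e-05), with 27 of 30 values above 0 and 0 members past the threshold. This call was lost with fry (adjusted p = 0.326) and in camera with an estimated correlation (adjusted p = 0.950). Without the late vector array the median was 0.097 (adjusted p = 0.0415, within a range of 1.17e-12 to 0.950 over 17 alternatives). The largest were RPS4X (0.57), RPL4 (0.50) and RPL5 (0.45).

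**Figure D3:**
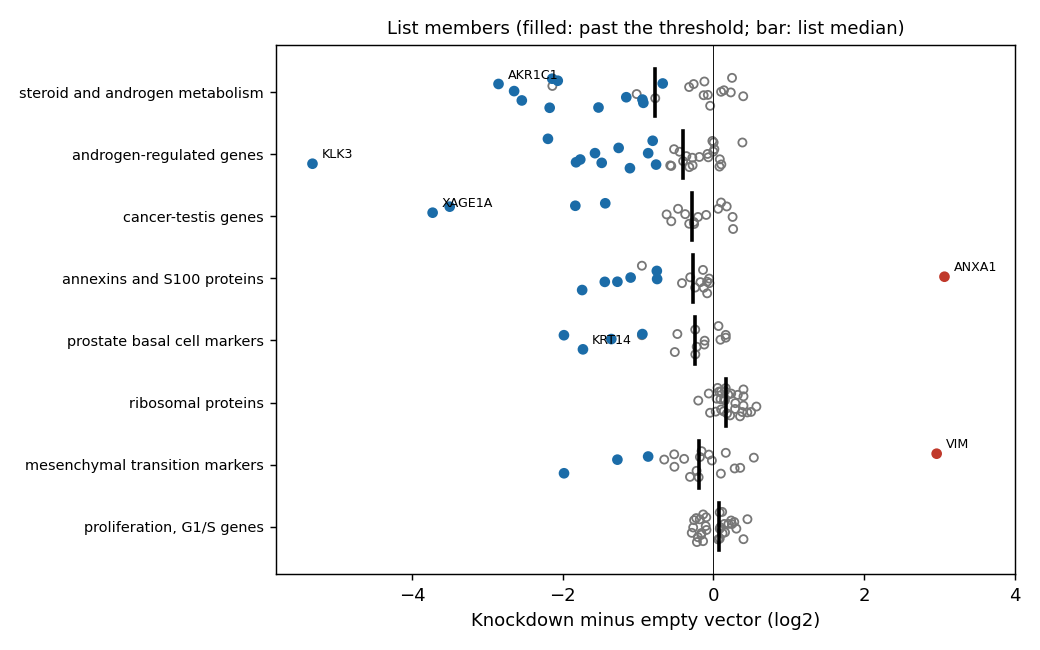
Knockdown minus vector difference (log2) of each measured member of the 6 lists called by camera and of 2 further lists. Filled points passed the threshold, open points did not, and the bar is the list's median. KLK3 lies at -5.32, and ANXA1 (3.07) and VIM (2.96) lie apart from the other members of their lists.

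The remaining 23 lists were not called by camera, and several of them held genes that moved in opposite directions. Among mesenchymal transition markers (adjusted p = 0.377), VIM rose while LOX (3.95-fold), S100A4 and SPARC (1.82-fold) fell, out of 20 measured. The caveolin gene CAV2 rose at least 1.63-fold but was at -0.040 with normexp, and the galectin gene LGALS1 fell 1.63-fold. Of 31 integrin and focal adhesion genes (0.820), ITGA2 (2.69-fold) and ITGA1 (2.24-fold) rose and LAMB1 (2.26-fold) fell. Of 27 luminal and adhesion markers (0.545), KRT19 (4.93-fold) and JUP (1.58-fold) fell. CDH1 (-0.01), FOXA1 (-0.01) and KRT8 (-0.24) did not pass. Among 19 neuroendocrine markers (0.421), SYT1 rose and UCHL1 (1.73-fold) fell. Of 34 proteases and inhibitors (0.124), 4 fell: SPINK1 (3.36-fold), MMP7 (1.94-fold), ADAMTS1 (1.66-fold) and SERPINB5 (1.59-fold). Among 9 CRISP and CAP-domain genes (0.672), CRISP3 and GLIPR2 (1.94-fold) fell, and CRISP1 rose 1.69-fold on a single probe, with the opposite sign (-0.68) when dim probes were included. Without the early knockdown array 1 protease, 1 luminal and 1 CRISP family gene fell, 2 mesenchymal markers rose and 1 fell, 1 neuroendocrine marker rose and 0 fell, and 0 integrin genes passed. Without the late one 1 protease, 1 luminal and 1 CRISP family gene fell, 1 mesenchymal marker rose and 2 fell, 2 neuroendocrine markers rose and 0 fell, and 1 integrin gene rose and 0 fell. Leaving out a vector array gave more falls: without the early one 5 neuroendocrine, 6 mesenchymal, 5 protease and 2 integrin genes fell, and without the late one 3 neuroendocrine, 5 mesenchymal, 5 protease and 5 CRISP family genes fell.

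Stress and metabolic lists held few changes. Of 33 interferon-stimulated genes (camera adjusted p = 0.974), IFI44 (2.08-fold) and IFI35 (1.96-fold) fell and CMPK2 (1.63-fold) rose. Of 22 NF-kB and inflammatory genes (0.929), the chemokine CXCL8 (3.43-fold) and TNFAIP3 (1.82-fold) rose, and TNFAIP3 was at -0.023 with normexp. Of 23 p53 targets (0.322), the cell cycle inhibitor CDKN1A (2.74-fold) and TP53I3 (1.96-fold) fell. Of 23 fatty acid genes (0.377), ACSL3 (2.34-fold) and ELOVL7 (1.80-fold) fell. AKR1B10 fell 1.61-fold among 22 NRF2 targets (0.545) but was at 0.34 without the early knockdown array. Among 24 Wnt and TGF-beta targets (0.545), CCN1 (1.67-fold) and BAMBI (1.55-fold) rose and RNF43 (1.77-fold) fell. Without either knockdown array in turn, 0 members of the p53, NF-kB, fatty acid, NRF2 and Wnt or TGF-beta lists passed. Of the interferon genes, 1 rose and 0 fell without the early one, and 0 passed without the late one. Without the early vector array 0 interferon genes rose and 4 fell, 2 NF-kB genes fell, and 0 Wnt or TGF-beta targets rose and 2 fell. Without the late one 2 interferon genes rose and 5 fell, 1 NF-kB gene fell, 3 fatty acid genes fell and 1 Wnt or TGF-beta target rose. No member passed in the G1/S (adjusted p = 0.426), G2/M (0.421), unfolded protein and ATF4 (0.124), hypoxia and glycolysis (0.124), cholesterol (0.545) and metallothionein (0.124) lists. The same held for the fibroblast (0.640), endothelial (0.971) and leukocyte (0.380) marker lists and for the small RNA machinery (0.756), with all 4 arrays. Without the early knockdown array 1 fibroblast marker and 1 hypoxia gene rose. Without the early vector array 1 fibroblast and 1 leukocyte marker fell and 1 cholesterol gene rose. Without the late vector array 2 leukocyte markers rose and 1 fell, 1 fibroblast marker and 1 hypoxia gene fell, and 1 unfolded protein or ATF4 gene rose. Adjusted over the list alone, 4 interferon genes rose and 8 fell, 2 p53 targets rose and 5 fell, and 1 mesenchymal marker rose and 5 fell. In the same terms 1 luminal marker rose and 2 fell, 1 neuroendocrine marker rose and 2 fell, 2 NF-kB genes rose and 1 fell, and 2 hypoxia genes fell. For the other lists reported here as not called, these counts were those over all genes. The interferon, NF-kB and small RNA lists had a median and mean below 0 but pointed up in camera.

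Passage, compared as late minus early with the vector group in the model, gave 1 gene past the threshold. MBL2, a lectin of the complement system measured by 1 probe, was 3.17-fold lower (log2 -1.67, SE 0.16, limma adjusted p = 0.0413), at -1.70 in the vector clone and -1.63 in the knockdown clone. The call was lost with quantile or median scaling and with the authors' value table. An unadjusted p under 0.05 was reached by 790 gene units. No gene with at least 2 probes passed, so those with the smallest p and the same direction in both clones are given, none of which pass. The higher ones were MAGEA10 (1.42), NANOS1 (1.19), ST3GAL6 (2.02), FMR1NB (1.43), BEX1 (1.53) and SLC35F4 (1.40) on the log2 scale, with limma adjusted p of 0.105 to 0.147. Early means of ST3GAL6 (-5.72), BEX1 (-5.57) and SLC35F4 (-6.35) lay below the lowest signals among probes well above background given for both groups. The sizes of these differences are therefore uncertain. The lower ones beside MBL2 were GCG (-1.31), TMIGD1 (-1.25), PLEK2 (-1.03), SLITRK3 (-1.56) and TMEM74B (-0.82), with adjusted p of 0.105 to 0.288. CRISP3 (-0.32), KLK3 (0.63), KLK2 (0.44), ANXA1 (0.45) and MSMB (-0.23) did not pass.

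Across gene lists, passage changes were called for cell cycle, lipid and metal-binding genes. In camera with an estimated correlation all 10 list calls were lost (adjusted p = 0.873 for each), and fry called 0. The estimated correlation rests on 1 residual degree of freedom here, so the loss in that setting decides little. G1/S, G2/M, cholesterol and unfolded protein genes had median changes larger in the knockdown clone, and fatty acid and ribosomal genes in the vector clone. Genes of G1/S (camera adjusted p = 1.21e-07, median -0.24) and of G2/M (6.94e-06, median -0.15) were lower at late passage, with 29 of 30 values below 0 in either list. PCNA (-0.41), MCM10 (-0.35), MCM6 (-0.34), BIRC5 (-0.40), CCNA2 (-0.38) and KIF20A (-0.34) had the largest values and did not pass. Per clone, the G1/S median was 0.06 in the vector and -0.52 in the knockdown clone, and the G2/M median was 0.01 and -0.37. Cholesterol genes were lower (8.92e-06), with medians of -0.06 and -0.37, and INSIG1 (-0.47), FDFT1 (-0.41) and EBP (-0.39) at the lower end. Metallothioneins were lower in both clones (1.78e-09), at -0.29 and -0.55, with MT1X at -0.62. Adjusted over the list alone, 6 of the 10 metallothioneins fell, but over all genes 0 did.

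**Figure D4:**
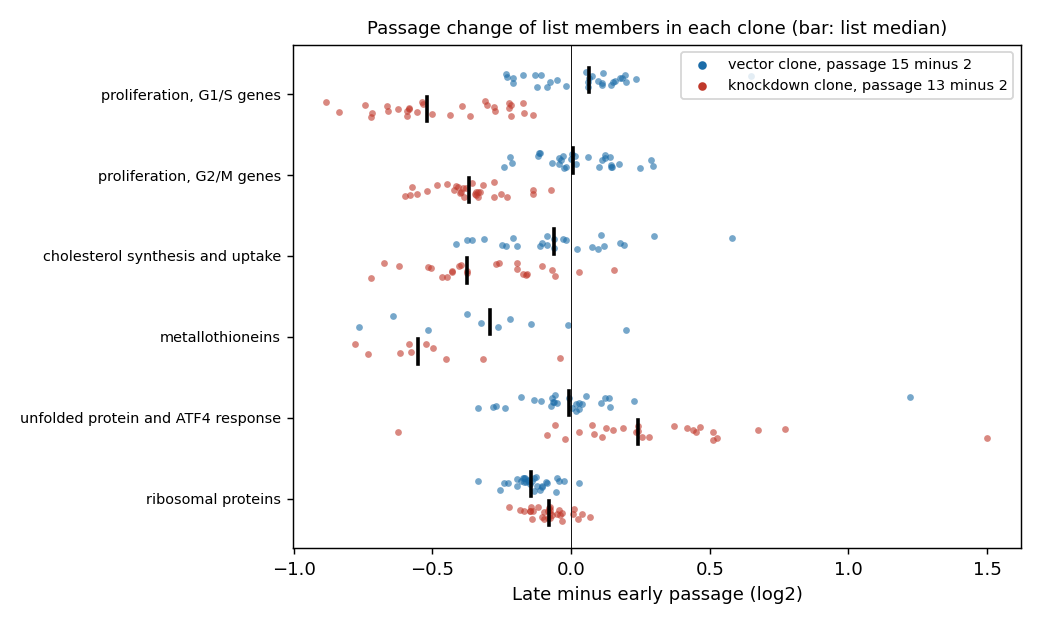
Late minus early difference (log2) of each measured member of 6 lists in the vector clone (passage 15 minus 2) and in the knockdown clone (passage 13 minus 2). Bars are list medians. The G1/S medians are 0.06 and -0.52, and the metallothionein medians -0.29 and -0.55.

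Smaller passage shifts were called in 6 further lists. Hypoxia and glycolysis genes (camera adjusted p = 0.00146, median -0.15, LDHA -0.42), fatty acid genes (0.00729, median -0.08, ELOVL6 -0.50) and steroid metabolism genes (0.0171, median -0.11, UGT2B10 -0.47) were lower. Their medians in the vector and knockdown clones were -0.14 and -0.20 for hypoxia, -0.14 and -0.02 for fatty acid and -0.16 and -0.23 for steroid genes. For ribosomal protein genes the medians were -0.14 and -0.08. Ribosomal protein genes were lower (0.00146, median -0.12), but under quantile scaling they pointed up (adjusted p = 0.126). Unfolded protein and ATF4 genes were higher (0.00729, median 0.11), with medians of -0.01 in the vector and 0.24 in the knockdown clone. DDIT3 was at 0.75, with 0.004 in the vector clone. Cancer-testis genes were higher (0.0226, median 0.04, mean 0.21), with PAGE4 at 0.88, but their median was below 0 with median centring (-0.009) and normexp (-0.033). None of these members passed.

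Passage changes of the clones did not run together. Across genes, the late minus early difference in the vector clone correlated at -0.005 with that in the knockdown clone, and 47.0% of units had the same sign. The other 19 lists were not called, with adjusted p from 0.0900 for androgen-regulated genes to 0.914 for integrins. Among them were the CRISP family, annexins and S100 proteins, luminal, basal, mesenchymal and neuroendocrine markers, proteases, interferon, NF-kB, p53, NRF2 and Wnt or TGF-beta genes, fibroblast, endothelial and leukocyte markers and the small RNA machinery. The integrin list had a median and mean above 0 but pointed down in camera, and the endothelial list had a median of 0.01 and a mean of -0.04. Adjusted over the list alone, 2 cancer-testis genes rose and 1 fell, 1 gene rose in each of the CRISP, androgen-regulated and fibroblast lists, and 1 fell in each of the neuroendocrine and endothelial lists. The additive model cannot test whether passage acted differently in the clones.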

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

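The tests of a change in the late knockdown array were chosen after the result was seen. With 2 arrays per group, no array could be tested as an outlier. The genes here come from those named in the knockdown comparison, and from the passage genes named in any case or by smallest p. The lists are those called for passage. In each result here, effects pointed in opposite directions in the groups being compared, and none of these differences was tested. Passage genes named only as list members, and lists not called, were left out. The endoplasmic reticulum gene SDF2L1 was higher in the knockdown clone by 1.82 at early passage and at -0.02 at late passage, a difference of -1.85. LUM went from 0.58 to -0.08, a difference of -0.66, and TEK from 0.54 to -0.03, a difference of -0.57. XPO5 went from -0.004 to 0.32, a difference of 0.32. From early to late passage MSMB changed by 0.10 in the vector clone and by -0.56 in the knockdown clone, a difference of -0.66. The list medians of passage change were 0.06 and -0.52 for G1/S genes (difference -0.58), 0.01 and -0.37 for G2/M genes (-0.38) and -0.01 and 0.24 for unfolded protein and ATF4 genes (0.25).

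Lower proliferation and cholesterol genes at late passage were weighed further. Scaling between the arrays does not account for them: the median of the 85 members lay at the 0.01th percentile of 10000 level-matched random lists, the lowest these can give, in both the main and the quantile scaling. Whether the late knockdown array alone changed cannot be told apart from an effect of passage in that clone, as each clone has 1 array per passage. Against the mean of the vector arrays, G1/S genes had a median of 0.25 in the early and -0.26 in the late knockdown array. The 55 G2/M and cholesterol genes had 0.023 and -0.29. The clones may differ in their baseline, so neither early value decides. A difference in growth between the cultures at harvest also stays open and untested.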

How the results depend on the processing

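The knockdown count of 801 became 2581 with normexp, 163 without the filter on dim probes, 1221 in genes with at least 3 probes, 1668 with an intensity trend and robust prior, and 362 with the untested 2-fold rule. It ranged from 166 to 1741 when an array was left out, where the lone array of a group was assumed to vary like the other group. Quantile (823) and median scaling (973), the all-array filter (902), the probe median (680), median polish (609) and the authors' table (774, all shared) stayed within 1.5 times. CRISP3 lost its call with the probe median (-1.53) and median polish (-1.51), and kept it in 13 of 15 alternatives, including each left-out array. The correlation of early and late differences was 0.48 without the filter. Replicate numbers marked early and late passage, and same-numbered arrays deviated from their group means with a correlation of -0.005, so they did not act as pairs. With the replicate block 1190 genes were called, 798 of them among the 801, and 7 lists.

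The 6 knockdown lists became 0 with an estimated correlation and 1 with fry, and ranged from 7 to 9 without an array. The 10 passage lists became 0 with either. The passage count of 1 became 0 with quantile or median scaling, no filter, the probe median, median polish, the authors' table or no vector group term (133 at an unadjusted p under 0.05 in the last). It became 31 with normexp, 36 with the all-array filter, 56 in genes with at least 3 probes and 73 with a trend and robust prior. Passage without an array could not be fitted, as no residual degrees of freedom remain.

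Some results turned direction: TNFAIP3 (-0.023) and CAV2 (-0.040) with normexp, CRISP1 (-0.68) without the filter, AKR1B10 without the early knockdown array (from -0.80 to 0.34 over the left-out arrays), ANXA13 without the late one (-2.30 to 0.73), and the ribosomal list in passage under quantile scaling (adjusted p = 0.126). Leaving out an array or the filter changes which probes enter, which may matter for CRISP1, AKR1B10 and ANXA13. Fewer genes were tested with at least 3 probes, and fewer arrays entered when 1 was left out. For the other changes the cause was not tested. Of the alternatives for named genes in the knockdown comparison, 1308 kept their side of the threshold, called or not, 171 lost a call, 54 gained one and 5 reversed. Without the early knockdown array 45 of the named genes lost the call, and without the late one 35. Signal over background limits the dim genes: 57 called genes were not well above background in 1 group.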

Other observations

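The gene families, the test of the clones and the shuffled correlation below were chosen after the values were seen. Among 294 families of genes sharing a symbol stem (588 one-sided Fisher's exact tests, Benjamini-Hochberg adjusted), 7 held more lower genes in the knockdown clone than the 446 of 13249 in the background, and 0 held more higher ones. Kallikreins fell in 5 of 15 cases (adjusted p = 0.0141): beside KLK3 and KLK2 these were KLK1 (5.68-fold), KLK8 (3.17-fold) and KLK5 (2.64-fold), all on chromosome 19. Keratins fell in 9 of 48 cases (adjusted p = 0.00523), all 9 on chromosome 17, including KRT19, KRT14, KRT15, KRT13 (2.02-fold) and KRT10 (1.66-fold). Caspases fell in 4 of 11 cases (adjusted p = 0.0339), with CASP14 (2.17-fold) and CASP10 (1.96-fold), each on 1 probe, beside CASP4 and CASP5. CASP6 (0.27), CASP8 (0.29) and CASP9 (-0.03) did not pass. Fisher's test takes genes as independent, but the called kallikreins, and likewise the called keratins, lie close together on their chromosome. The same holds for many of the UGT and AKR genes below. On chromosome 11 it also holds for CASP4 and CASP5, and for TRIM5, TRIM22 and TRIM34 of the TRIM genes below. A regional difference is then counted several times, so these adjusted p-values may be too small.

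Members of the UGT family fell in 8 of 14 cases (adjusted p = 2.29e-06) and aldo-keto reductases in 7 of 11 (4.04e-06), among them AKR1D1 (4.02-fold) and AKR1B1 (2.24-fold). Genes of either family resemble each other, so probes can read several of them. TRIM genes fell in 9 of 65 cases (0.0339), but several of these are near-identical copies of TRIM49 with few probes. SOX genes fell in 4 of 12 (0.0425), with SOX30 at least 2.70-fold and SOX11 2.14-fold lower. Under quantile scaling 5 UGT, 5 AKR, 8 keratin, 5 kallikrein, 4 caspase, 9 TRIM and 2 SOX genes fell and 0 rose. The medians of all 7 families stayed below 0 under quantile and median scaling, but so did the median over all gene units (-0.022 and -0.059). The caspase medians (-0.011 and -0.032) lay above these, so caspases as a family were not lower than genes in general.

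Lower androgen-regulated genes formed a pattern of interest. Scaling of the brighter knockdown arrays does not account for it, since the list's median of -0.40 lay at the 0.01th percentile of level-matched random lists in both scalings. Whether loss of CRISP3 or a difference between the clones lowered these genes cannot be told apart with 1 clone per group. Cells of another type in the knockdown arrays also stay open here. Hence a link between CRISP3 and androgen response stays a hypothesis that further clones could test.

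Neighbouring genes also changed together. In 835 windows of 20 consecutive genes, the SD of window medians was 0.125 at early and 0.131 at late passage, against at most 0.094 and 0.092 in 1000 shuffles of gene order. With 1 gene per name stem the SD was 0.118 at early and 0.119 at late passage, still at least 1.38 times the shuffled mean. Probes shared between copies of the same name stem thus do not account for all of it. Copies with unlike names on the array stayed in, so shared probes are not excluded. Window medians of both passages correlated at 0.48, above the 0.33 on average and 0.43 at most in 1000 shuffles, which is consistent with a regional difference, such as copy number, between the clones. The lowest window, on chromosome 4 (68918916 to 71384489, hg19), holds UGT2 genes among others. Over all genes of that window the medians were -0.32 at early and -0.91 at late passage. The highest window, on chromosome 19 (20117932 to 23836834), had medians of 0.41 and 0.30. Both come from the run with all genes, so copies that may share probes were not removed from them. Other regional causes, such as shared chromatin state, were not tested.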
